A study of Dunaliella salina with 12 samples.

How the data were processed

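RNA sequencing libraries were made from Dunaliella salina, a unicellular green alga of salt lakes that balances external salt with intracellular glycerol. Cells were kept at 25 °C with 16 h of light and 8 h of dark at 8000 lx and are labelled as 5 days old. They were moved for 2 h into fresh medium holding 1.5 M NaCl, either alone (control) or with a further 1.5 M NaCl, with 1.5 M sorbitol or with 0.4 mM H2O2. Each of the 4 groups had 3 libraries, and 12 libraries were used. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

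The submitters' processing notes name cutadapt, an adapter trimmer, and RSEM, a program that estimates transcript abundance. Their versions, the reference and its build are not given in the sources used here. The deposited values were read as FPKM, fragments scaled by transcript length and by the mapped total. No source states this unit, and it was inferred from the values: they have 2 decimals, are never negative, and sum to between 1065190 and 1133348 per library. That range is neither that of counts nor the fixed sum of TPM. The table lists 82333 assembled genes, of which 4943 are at 0 in every library. Their IDs have a component part and a gene part, as a de novo assembly gives them. There are 73348 components, and 68677 of these hold 1 gene of the table. None of the IDs (0) matched the reference table of 16683 genes of the assembly Dunsal1 v. 2, and the files do not pair IDs with names. The 25 gene lists fixed in advance, among them glycerol synthesis, starch breakdown and antioxidant enzymes, therefore could not be run.

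The values hold no absolute depth. Relative depth was estimated from the steps that single reads make among genes between 0.2 and 1.2 FPKM, as the most frequent step ratio to a control library within a window of 0.05 log2. Between 19.0% and 29.8% of the compared genes lay at that main step. Relative depth ran from 0.909 to 1.203 around a mean of 1.0, so no library was much shallower than the others. A value of 0 says only that a gene is listed at 0.

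Values were analysed as log2(FPKM + 1), a scale that understates changes of low genes. Genes with at least 1 FPKM in at least 3 libraries were tested, 27038 in all. One limma model (version 3.58.1, R 4.3.3, mean-variance trend) held all 12 libraries, and 5 comparisons were taken from it. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and an adjusted p of 0.05 was the threshold. Every adjusted p below comes from limma. The 5 comparisons, the overlaps of calls, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Exceptions are stated where they occur. Estimates from different libraries alone and the ranking of abundant control genes were not part of this plan. Neither were the groups by level of expression and the counts of genes present in some groups only. Count-based models had been planned in case the values were counts and were not used. With no names to go by, the rule gave for each comparison the 2 higher and 2 lower IDs with the largest fold change among called genes. They also had to be at or above the median level over all libraries, with the 3 libraries of one group all above those of the other. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

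The model was tested on simulated data for the 27038 genes, with 100 genes changed by 1 log2 and 100 by 2 log2, under 2 kinds of noise. The changed genes were drawn from those at or above the median level, so recovery of lower genes was not tested. With each gene's own residuals resampled, the NaCl comparison recovered 76 and 99 of them and called 25 unchanged genes, 12.5% of its calls. The sorbitol comparison recovered 77 and 97 and called 19 unchanged genes, 9.84% of its calls. The H2O2 comparison recovered 78 and 97 and called 20 unchanged genes, 10.3% of its calls. These shares are above the nominal 5%. Normal noise was added after the resampled result had been seen. It gave 84 and 98 with 7 unchanged genes called for NaCl, 88 and 100 with 10 for sorbitol, and 89 and 99 with 2 for H2O2. Which noise is closer to that of the libraries was not settled, so the true share of false calls may exceed the nominal one. The simulated shares also belong to a setting with far fewer changed genes than NaCl or sorbitol called. For H2O2 the setting held more changed genes than the 30 that were called, so its share of false calls may exceed the simulated one.

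Overlaps of calls against the shared controls were set beside independent lists (n1 × n2 / N per direction) and beside 20 simulations of unchanged groups against the same controls. Sizes and correlations of effects were also estimated from products of different libraries alone, so that the noise of a library does not enter, with ranges from leaving out each library in turn. Alternatives fixed in advance were quantile normalization, no mean-variance trend, no filter or a filter at 5 FPKM, a pseudocount of 0.1, a fit of only the groups compared, the replicate number as a block, each library left out, an absolute log2 fold change of at least 1, and an adjusted p of 0.01. Alternatives added after the data were seen were median-ratio scaling, rescaling to equal sums, sums per component, components with 1 gene, and leaving out genes at 0 in the sorbitol libraries alone.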

Results

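Transcript levels were measured in 12 libraries of D. salina after 2 h in control medium, added NaCl, sorbitol or H2O2, with 3 libraries per group. The libraries listed between 37005 and 42727 assembled genes above 0 and between 23391 and 27145 at 1 FPKM or more. H2O2 libraries had the lowest mean number of genes above 0, 37827 ± 151 (SD, n = 3), against 41622 ± 910 in control. Their mean relative depth was 0.926 ± 0.021, against 1.052 ± 0.132 in control, 1.037 ± 0.115 with NaCl and 0.985 ± 0.064 with sorbitol. Pearson correlations of log2(FPKM + 1) across genes were 0.925 to 0.934 within control, 0.899 to 0.911 within NaCl, 0.937 to 0.942 within H2O2 and 0.941 to 0.948 within sorbitol. Between control and NaCl libraries they were 0.876 to 0.901, and between control and H2O2 libraries 0.926 to 0.938, close to the range within control. Genes are not independent replicates, so these values describe the libraries only. Of the genes above 0 in either library of a pair, at most 3.64% had exactly equal values in both.

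**Figure D1:**
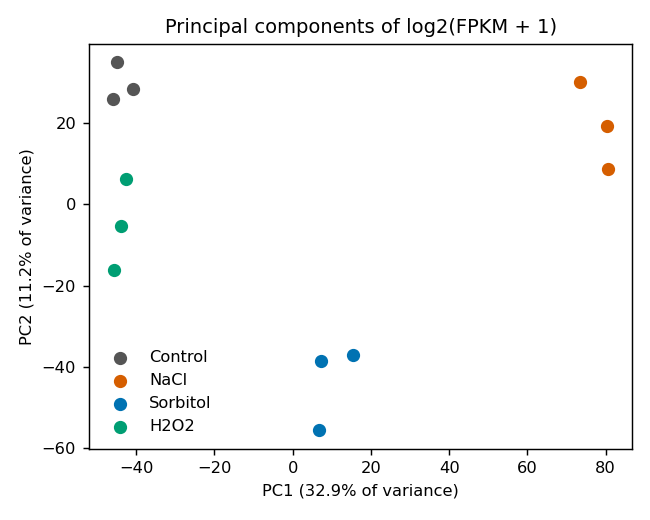
Principal components of log2(FPKM + 1) over the 27038 tested genes, 1 point per library, with PC1 (32.9% of variance) on the x axis and PC2 (11.2%) on the y axis, colored by group. The NaCl libraries lie at 73.4 or more on PC1, the sorbitol libraries between 6.84 and 15.4, and the control and H2O2 libraries at -40.8 or below. On PC2 the control libraries lie between 25.9 and 34.8 and the H2O2 libraries between -16.3 and 6.21.

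The series title ties salinity to osmotic and oxidative stress and to glycerol made from starch. Added NaCl against control gives the response to salinity as a whole. NaCl changed 9681 of the 27038 tested genes (35.8%), 4966 higher and 4715 lower. The balance turned with the scaling of libraries, to 4311 higher and 5359 lower under median-ratio scaling and 5533 higher and 4309 lower with equal sums. Changes of at least 1 log2 numbered 3534, and more of these were lower (2081) than higher (1453). The gene c1320_g1 rose from 33.8 ± 1.88 to 1736 ± 83.8 FPKM (SD, n = 3), a log2 fold change of 5.64 ± 0.25 (SE, adjusted p = 2.2e-08). The gene c30948_g2 rose from 4.56 ± 0.15 to 249 ± 9.62 FPKM (5.49 ± 0.14, adjusted p = 7.9e-10). The gene c77213_g1 fell from 51.5 ± 4.15 to 1.33 ± 1.27 FPKM (-4.67 ± 0.38, adjusted p = 1.5e-06). The gene c29414_g1 also fell (-4.59 ± 0.60, adjusted p = 8.3e-05), but its control libraries were uneven, at 3559, 1665 and 555 FPKM, against 55.1, 35.7 and 114 with NaCl. The files do not pair these IDs with names, so their functions are not given here.

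Of the 10 genes with the highest mean in control, 5 were lower with NaCl, 0 were higher and 5 did not pass the test. The ranking uses the control libraries of the test itself, so it favors falls and leaves out genes abundant only with a treatment. In the highest of 4 equal groups by mean level over all libraries, NaCl called 2363 genes higher and 1778 lower. The gene of rank 1 went from 31492 ± 4236 to 11368 ± 1761 FPKM, and that of rank 2 from 31291 ± 5662 to 6969 ± 1326 FPKM. The gene of rank 4 went from 16339 ± 3100 to 2337 ± 910 FPKM, and that of rank 8 from 6732 ± 369 to 1696 ± 350 FPKM. Their log2 fold changes were -1.47, -2.17, -2.86 and -2.01, with a largest adjusted p of 8.3e-06. The gene of rank 3 was at 18917 ± 746 FPKM in control and 20016 ± 1258 with NaCl and did not pass (adjusted p = 0.35). In each library the 10 highest genes of that library held 13.1% ± 0.89 of the summed FPKM in control, 9.30% ± 0.44 with NaCl, 9.57% ± 0.21 with sorbitol and 11.9% ± 0.78 with H2O2.

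**Figure D2:**
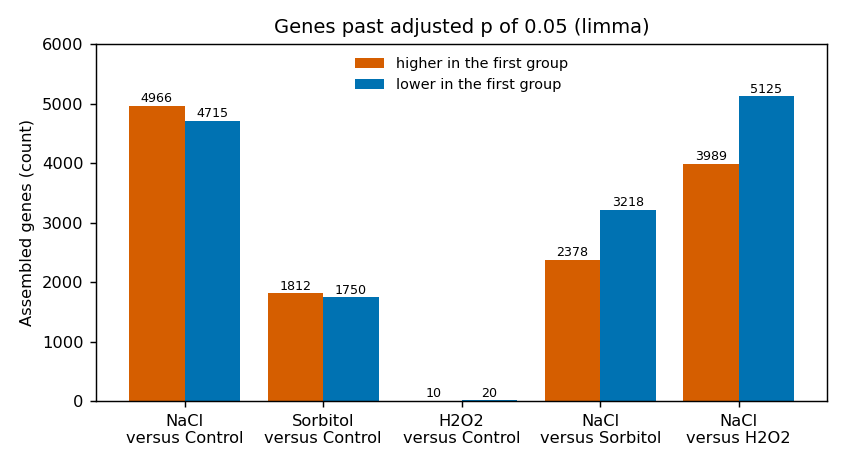
Number of assembled genes past an adjusted p of 0.05 in limma (y axis) in each of the 5 comparisons (x axis), with orange bars for genes higher and blue bars for genes lower in the group named first. NaCl against control gave 4966 higher and 4715 lower genes, and H2O2 against control 10 and 20.

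Sorbitol raises the external osmotic strength without added salt, so its comparison with control addresses a hypertonic step. This step is weaker than that of the added NaCl, since dissolved NaCl gives more particles per mole. Sorbitol changed 3562 genes, 1812 higher and 1750 lower. Of the changes of at least 1 log2, 712 were lower and 288 higher. The gene c1320_g1 rose to 715 ± 206 FPKM (4.33 ± 0.25, adjusted p = 2.2e-06), and c24523_g1 rose from 3.6 ± 1.42 to 78.3 ± 12.9 FPKM (4.14 ± 0.29, adjusted p = 8.6e-06). The gene c31198_g1 fell from 109 ± 22.3 to 1.92 ± 0.62 FPKM (-5.23 ± 0.36, adjusted p = 6.3e-06), and c30955_g1 from 21.1 ± 1.38 to 0.41 ± 0.15 FPKM (-3.98 ± 0.41, adjusted p = 9.7e-05). Of the 10 most abundant control genes, 4 were lower with sorbitol, those of ranks 1, 2, 4 and 8. In the highest of the 4 groups by mean level over all libraries, sorbitol called 1025 genes higher and 699 lower. The split of calls moved with the scaling of libraries. The share of higher genes was 50.9% as given, 34.5% under median-ratio scaling (1208 higher, 2298 lower) and 63.9% with equal sums (2679 higher, 1512 lower). The count was 2301 without control replicate 2, 2353 without sorbitol replicate 1 and 2214 without sorbitol replicate 3.

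Some genes that fell with sorbitol differed in level within the NaCl group. Of the 712 genes lower by at least 1 log2, 40 were at 0 in the sorbitol libraries alone. Of the rest, 214 had an H2O2 log2 fold change of -1 or below and 458 one above it. The split itself uses no NaCl value, but the 40 genes left out were chosen partly by NaCl values above 0. The median FPKM of the 214 was 2.62, 2.51 and 3.06 in the control libraries, 1.08, 1.51 and 0.52 in NaCl replicates 1, 2 and 3, 0.46, 0.44 and 0.14 in the H2O2 libraries, and 0 in each sorbitol library. NaCl replicate 3 was below both other NaCl libraries in 65.4% of the 214 and in 36.2% of the 458, against 24.8% of all tested genes. Both genes named as lower with sorbitol had this order. In NaCl replicates 1, 2 and 3 the gene c31198_g1 was at 104, 172 and 71.5 FPKM and c30955_g1 at 16.7, 28.4 and 6.07 FPKM, and their H2O2 means were 29.9 ± 15.3 and 4.05 ± 1.58 FPKM. This grouping was made after the values were seen, and the shares are not matched on level. Without NaCl replicate 3 the sorbitol count was 3488.

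NaCl and sorbitol changed many of the same genes in the same direction. Both comparisons called 2949 genes in the same direction, 1524 higher and 1425 lower, and 33 in opposite directions. Independent lists of these sizes would share 638. Simulations of unchanged groups against the same controls shared 0, but such groups call almost no genes, so this is not the overlap that shared controls bring to long lists. When the 3 control libraries were divided between the comparisons, 1 for one and 2 for the other, 848 to 1800 genes were shared in the same direction over the 6 arrangements, where independent lists would share 158 to 282. A lone control library was assumed there to vary like the other groups, and this check was added after the data were seen. The correlation of the log2 fold changes across genes was 0.65. Shared controls gave 0.50 between simulated unchanged groups, and their covariance gives 0.136 at the spread of these fold changes. The covariance was 0.281 against 0.059 in the simulations. Estimated from different libraries alone, without the noise of single control libraries, the covariance was 0.215 (0.204 to 0.225 with each library left out) and the correlation 0.73 (0.70 to 0.76). A deviation common to the 3 control libraries would stay in both values. The overlap was 1918 without control replicate 2 and 1840 without sorbitol replicate 3.

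**Figure D3:**
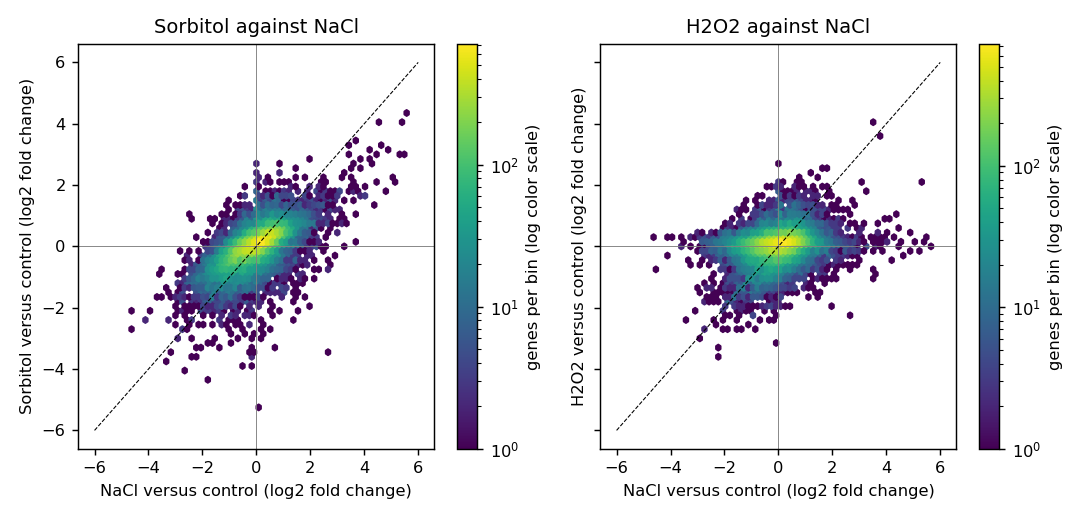
Log2 fold changes against control of the 27038 tested genes, with NaCl on the x axis and sorbitol (left) or H2O2 (right) on the y axis, as hexagonal bins colored by the number of genes on a log scale, with a dashed line of equal change. The correlation across genes is 0.65 at the left and 0.27 at the right, where the covariance from shared controls gives 0.136 and 0.178 at the spread of these fold changes.

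NaCl against sorbitol asks what differs between added salt and an added sugar alcohol of the same molarity. The treatments differ in osmotic strength as well as in salt. This comparison called 5596 genes, 2378 higher with NaCl and 3218 lower. Of the 2949 genes changed the same way by both, NaCl lay further from control in 1334, sorbitol did in 25, and 1590 were not shown to differ. Another 6699 genes were called with NaCl and not with sorbitol, and the direct test separated the treatments in 3272 of these. The genes lower with NaCl than with sorbitol by the naming rule were c17757_g1, at 0.89 ± 0.78 against 16.8 ± 7.40 FPKM (-3.26 ± 0.46, adjusted p = 0.00035), and c27136_g1, at 0.59 ± 0.08 against 9.96 ± 1.79 FPKM (-2.77 ± 0.20, adjusted p = 6.3e-06). The higher ones were c31198_g1 (5.25 ± 0.36, adjusted p = 5.2e-06) and c22761_g1 (3.82 ± 0.83, adjusted p = 0.0061). Neither of these was called between NaCl and control (log2 fold changes 0.02 and -0.09). The gene c22761_g1 was at 30.0, 50.2 and 8.84 FPKM in NaCl replicates 1, 2 and 3, again lowest in replicate 3.

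H2O2 against control addresses the oxidative part. It changed 30 genes, 10 higher and 20 lower. An unadjusted limma p below 0.05 was reached by 3235 genes, where 5% of the 27038 tested would be expected with no change. The SD of H2O2 effects, estimated from different libraries alone, was 0.212 (0.174 to 0.233 with each library left out), against 0.434 with sorbitol. At or above the median level it was 0.117 (0 to 0.157). In the simulation with resampled residuals, which held more changed genes than H2O2 called, this comparison called 20 unchanged genes. The gene c20697_g3 rose with H2O2 to 20.2 ± 3.37 FPKM (3.58 ± 0.53, adjusted p = 0.030) from 4.36, 0 and 0 in the control libraries, and also rose with NaCl (3.69) and sorbitol (3.39). The gene c26525_g1 rose from 11.2 ± 1.46 to 24.5 ± 5.47 FPKM (1.04 ± 0.15, adjusted p = 0.030). The gene c70079_g1 fell from 19.6 ± 4.15 to 7.64 ± 0.73 FPKM (-1.24 ± 0.18, adjusted p = 0.030). The gene c28807_g1 fell from 120.0 ± 9.44 to 62.9 ± 11.7 FPKM with H2O2 (-0.94 ± 0.13, adjusted p = 0.024), whereas it rose to 1382 ± 110 FPKM with NaCl (3.51 ± 0.13) and to 519 ± 69.4 with sorbitol (2.10 ± 0.13). Fitted with only the libraries of control and H2O2, these 4 genes did not pass (adjusted p = 0.15 to 0.23), and over all alternatives their adjusted p ran from 0.00040 to 0.23. Of the 30 genes, 20 changed the same way with both other treatments, and 1 was called with neither. The 3 treatments share the controls, so a deviation of the control libraries moves a gene the same way in each. Of the 20 lower genes, 7 were listed at 0 in all 9 treated libraries, and of the 10 higher genes 2 were at 0 in all controls. NaCl and H2O2 called 22 genes in the same direction and 3 in opposite ones, where independent lists would share 5.32. The simulations of unchanged groups shared 0.05 on average, with the same limit as above, and with the control libraries divided H2O2 had 0 to 5 calls, of which 0 to 4 were shared with NaCl in the same direction and 0 were opposite, where independent lists would share 0 to 0.52. Their fold changes correlated at 0.27 across genes, where shared controls gave 0.50 between unchanged groups and their covariance gives 0.178 at the observed spread. The covariance was 0.088 against 0.059. From different libraries alone, the correlation with H2O2 was 0.159 (0.114 to 0.199 with each library left out) for NaCl and 0.538 (0.450 to 0.650) for sorbitol. A deviation common to the control libraries would stay in these correlations and in the SD of H2O2 effects too. Below the median level the covariance with H2O2 was 0.074 for sorbitol and 0.017 for NaCl, and at or above it 0.018 and 0.021. At or above the median level the correlations were 0.385 for sorbitol and 0.237 for NaCl, at least 0.290 and 0.117 with each library left out. They had no upper limit there, since the SD of H2O2 effects reached 0 in a left-out fit.

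The H2O2 count depended on settings and on single libraries. It was 1 with only control and H2O2 libraries fitted, 0 with the replicate number as a block and 0 in limma at an adjusted p of 0.01. With no filter it was 12, at 5 FPKM 11, with a pseudocount of 0.1 12, for components with 1 gene 15 and without the mean-variance trend 102. The count was 1 without control replicate 1, 1 without control replicate 2 and 5 without control replicate 3. It was 4, 12 and 5 without H2O2 replicates 1, 2 and 3. It was 16 and 15 without sorbitol replicates 1 and 2, and 72 without NaCl replicate 3, which enters this comparison only through the shared fit. The share of higher genes was 33.3% as given, 20% under median-ratio scaling (7 higher, 28 lower) and 46.9% with equal sums (15 higher, 17 lower).

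NaCl against H2O2 called 9114 genes, 3989 higher with NaCl and 5125 lower. The gene c1320_g1 was at 35.7 ± 15.3 FPKM with H2O2 (NaCl against H2O2 5.65 ± 0.25, adjusted p = 2.8e-08), near its control level. The gene c24088_g1 was at 1176 ± 67.8 FPKM with NaCl and 28.2 ± 7.28 with H2O2 (5.36 ± 0.17, adjusted p = 2.3e-09). Lower with NaCl were c77213_g1, at 66.4 ± 16.7 FPKM with H2O2 (-5.0 ± 0.38, adjusted p = 9.4e-07), and c30130_g1, at 2.42 ± 0.61 with NaCl against 74.0 ± 12.9 FPKM (-4.45 ± 0.18, adjusted p = 1.4e-08).

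**Figure D4:**
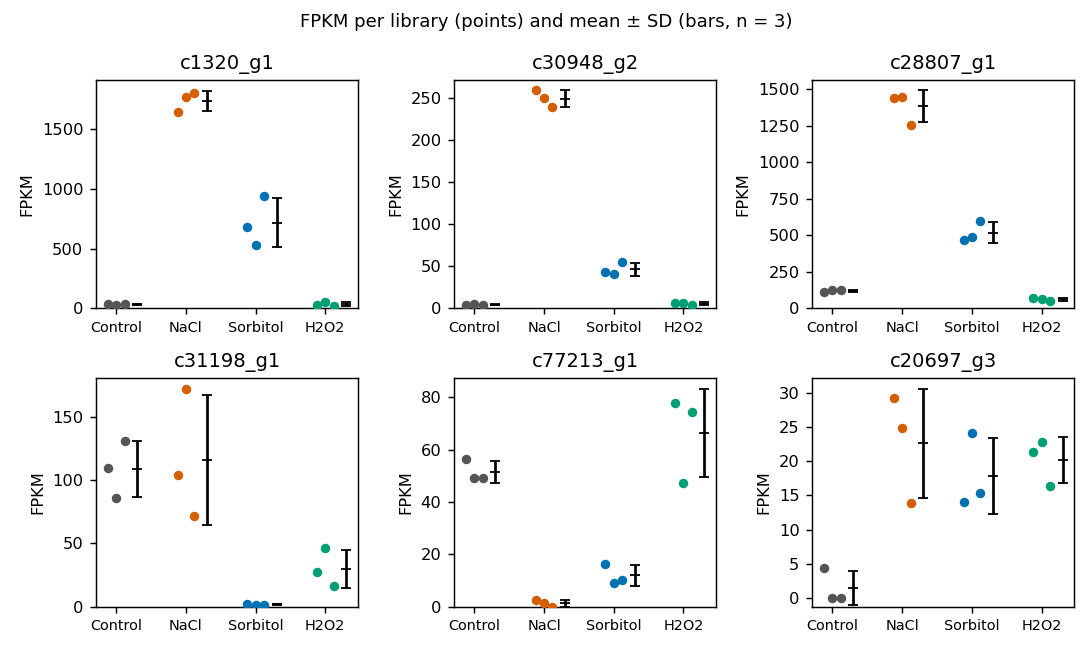
FPKM of 6 named genes (y axes) in each library (points) by group (x axes), with the mean and SD (bars, n = 3). The gene c28807_g1 averages 1382 FPKM with NaCl, 519 with sorbitol, 120.0 in control and 62.9 with H2O2, and c31198_g1 averages 1.92 FPKM with sorbitol against 109 in control.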

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

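The values hold no absolute depth, so changes of low genes are limited by an unknown number of reads. The alternatives by median-ratio scaling, equal sums, components and genes at 0 in sorbitol were chosen after the data were seen. Leaving out genes at 0 in the sorbitol libraries alone gave 3508 sorbitol calls. The named H2O2 genes lost the threshold in 43 of 84 alternative values, the other comparisons' in 0 of 84 each, and 0 values reversed. The gene lists and their estimated correlations were not run, for lack of names.

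Counts are given in the order NaCl, sorbitol and H2O2 against control, NaCl against sorbitol, NaCl against H2O2, then the overlaps of NaCl with sorbitol and with H2O2. Requiring at least 1 log2 left 3534, 1000, 22, 1471, 3515, 660 and 14, and an adjusted p of 0.01 left 6665, 1646, 0, 3285, 6426, 1416 and 0, since fewer genes can pass. Components with 1 gene, which leave 18372 genes, gave 5804, 2023, 15, 3205 and 5491. With no filter, and 77390 genes, sorbitol had 2337 calls, H2O2 12, and the overlaps were 1924 and 9. For the rest the cause was not tested. H2O2 calls and their overlap with NaCl were 102 and 74 without the mean-variance trend, 11 and 7 at 5 FPKM, 12 and 6 with a pseudocount of 0.1, and 1 and 1 with only the groups compared. Leaving out each library gave 8210 to 10151, 2214 to 4181, 1 to 72, 4133 to 6078, 8054 to 8974, 1840 to 3470 and 0 to 35. The overlap with H2O2 was 1, 0 and 5 without control replicates 1, 2 and 3, 3, 6 and 4 without H2O2 replicates 1, 2 and 3, 12, 11 and 14 without the sorbitol replicates, and 35 without NaCl replicate 3.

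Same-numbered libraries did not deviate together (correlations -0.083 to 0.047 over 18 pairs), and 3 of 12 libraries correlated best with their own number, so the numbers were not taken as pairs. With the replicate number as a block the counts were 9041, 2859, 0, 4973 and 8608, the overlap of NaCl with H2O2 was 0, and the 4 named H2O2 genes had an adjusted p of 0.085 to 0.104.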

Other observations

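The tests on genes at 0 with sorbitol, on depth, on a common response at different sizes and on an H2O2-like part of the NaCl response were chosen after the result was seen. The scaling test and the test by level of expression were written before their values were seen.

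Genes called with NaCl and sorbitol were more frequent at higher expression levels. When tested genes were ranked by mean level into 4 equal groups, NaCl called 6.43%, 29.0%, 46.5% and 61.3% from the lowest to the highest, and sorbitol 4.28%, 8.34%, 14.6% and 25.5%. The scale understates changes of low genes, so this gradient may reflect the power of the test. Sorbitol calls were 23.5% higher genes in the lowest group and 59.5% in the highest, a split that moves with the scaling of libraries as given above. A comparison of sorbitol with H2O2, added after the data were seen, called 2786 genes, 1071 higher with sorbitol and 1715 lower. Genes at 1 FPKM or more in all 3 libraries of a treatment and at 0 in all controls numbered 51 with NaCl, 47 with sorbitol and 22 with H2O2. The reverse pattern held for 88, 124 and 70 genes.

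Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.1. The real split gave the highest count in each, so that 1 of 10 reached it. The real counts and the highest of the other splits were 9681 and 9 for NaCl, 3562 and 6 for sorbitol, 30 and 9 for H2O2, 5596 and 4 for NaCl against sorbitol, and 9114 and 7 for NaCl against H2O2. The other splits mix libraries of both groups, so a difference between the groups adds to their spread and lowers their counts. Those counts are therefore not the ones that unchanged groups would give. A test of any difference among the 4 groups called 9797 genes, and the highest of the other regroupings of the 12 libraries called 2874. Only the real grouping, 1 of 100, reached that count. A random assignment of libraries to groups can therefore be excluded for this test at the 0.05 level. The test cannot separate a treatment from another difference between the groups, such as a culture shared by the libraries of a group.

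A set of 194 genes was listed at 0 in all sorbitol libraries and above 0 in the other 9, against 11, 34 and 20 such genes for control, NaCl and H2O2. These genes lay at low levels. Their median FPKM was 0.655 to 0.985 in the control libraries, 0.14 to 0.27 in the H2O2 libraries and 0.265 in NaCl replicate 3. Only 70 of them were among the tested genes. Lower depth is argued against, since sorbitol libraries had a mean relative depth of 0.985, above the 0.926 of H2O2. A response to sorbitol alone is argued against by the H2O2 libraries, where the set's median log2 ratio to control was -1.871, outside -0.066 to 0.151 for 10000 lists of matched level. RNA from another source, carried in amounts that differed between libraries, is a candidate explanation. The set's median log2 ratio of NaCl replicate 3 to replicates 1 and 2 was -1.486, outside the matched -0.119 to 0.157. In 214 other genes lower with sorbitol, taken by an H2O2 log2 fold change of -1 or below, the median difference between these libraries was -0.64. That value is on the log2(FPKM + 1) scale, which shrinks differences of low genes, and has no matched range. It cannot be set against the -1.486, a ratio of FPKM. H2O2 called only 20 genes lower in all, so most of the 214 did not pass the test for H2O2. A change of the alga that varied between cultures stays open, no source can be named without gene names, and part of the sorbitol calls may belong to this pattern.

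NaCl changed 2.72 times as many genes as sorbitol, 4.24 times without sorbitol replicate 3, and 2.35 to 4.24 times over all alternatives. Scaling by a few abundant genes is argued against, as the ratio was 2.76 under median-ratio scaling. Depth is argued against, as the SD of effects from different libraries, which depth does not inflate, was 1.56 times larger with NaCl (1.51 to 1.60 with each library left out). The effects of NaCl and sorbitol were not proportional across genes. They correlated at 0.73 (0.70 to 0.76), at 0.83 (0.81 to 0.85) among genes at or above the median level, and at 0.65 below it. A common response that is not proportional, or group differences other than the treatment, would also lower this correlation. A single common response at different sizes is therefore not excluded. The osmotic step was stronger with NaCl, since dissolved NaCl gives more particles per mole. An ion-specific part and this stronger step may each contribute. Neither was tested, and the design cannot tell them apart.

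An H2O2-like part of the NaCl response that sorbitol lacks was tested by correlating, across genes, NaCl minus sorbitol with H2O2 minus control, which share no library. The correlation was -0.11 (-0.13 to -0.06 with each library left out), but its sign also reflects the covariance of sorbitol with H2O2, 0.049 against 0.023 for NaCl with H2O2, and so does not decide the matter. Among genes at or above the median level it was 0.023 (-0.045 to 0.091). The negative value may therefore rest on low-level genes with lower estimates in both sorbitol and H2O2. Of the 194 genes above, only 70 were tested and entered this correlation. For the more abundant genes the range spans 0, and an H2O2-like part cannot be told apart from none.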
